A study of Mus musculus with 6 samples.

How the data were processed

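Polyadenylated RNA was sequenced from primary mouse aortic smooth muscle cells in 6 libraries, 3 labelled WT and 3 labelled Bmal1 KO. Cells were grown, per the labels' protocols, in DMEM with 10% fetal bovine serum at 37 °C and 10% CO2. They were then kept for 7 days in medium with hydrogen peroxide at 0.3 mM and glucose at 4.5 g/L. Libraries were made from 1.0 µg of total RNA with an Illumina stranded mRNA kit, per the labels' protocols. Trimmomatic, HISAT2 and featureCounts with the mm10 genome are named in the submitters' processing notes, without versions or roles. The annotation and strand setting used for counting are not given in the sources used here. Groups and replicate numbers came from the sample titles, and 0 columns of the table stayed unmapped. The labels give all libraries the same batch.

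The authors' deposited table holds 27179 genes by NCBI Gene ID, with a non-negative signal per library in the form of normalized read counts. In the deposited table every non-zero signal was a whole multiple of 1 step per library. Dividing by the step gave whole reads for 100% of values within 0.01. The implied factors of the libraries (1.09, 1.21 and 1.09 for WT, 0.981, 0.834 and 0.875 for Bmal1 KO) equalled median-ratio size factors recomputed from the recovered reads. This scaling assumes that most genes do not differ, or differ evenly in both directions. Recovered totals ran from 32503525 to 44657471 reads per library, with 18650 to 19398 genes with reads.

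Raw counts had been assumed before the data were examined, with edgeR's quasi-likelihood test as the planned main test. Since the deposited signal is normalized, the main test was limma on log2(value + 1) with a mean-variance trend (eBayes with trend), over genes with a value of at least 10 in at least 3 libraries. The planned edgeR test on recovered reads became an added alternative and called 11485 genes. Group was the only term, and differences are libraries labelled Bmal1 KO minus WT. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and every adjusted p of a gene is from limma unless another test is named. Log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes, while folds are ratios of mean normalized counts. A gene with no reads in a group was given a bound against a floor of 3 reads over that group's 3 libraries. Ratios of genes with 1 to 9 reads in a group carry exact 95% intervals. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Software versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

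A set of 30 gene lists was fixed before the data were examined. The main ones were CLOCK:BMAL1 targets, contractile genes and bone and cartilage genes. The others covered further clock genes, calcification inhibitors, matrix, proteases, inflammation, interferon response, antioxidant response, NADPH oxidases, proliferation, p53 and senescence, endoplasmic reticulum stress, glycolysis and hypoxia, oxidative phosphorylation, lipid synthesis, TGF-beta and BMP signalling, Wnt signalling, autophagy, immediate early and heat shock genes, sex-linked genes and markers of endothelial, macrophage, fibroblast, adipocyte, mesothelial, Schwann and striated muscle cells. All but the sex-linked list, 29 in number, were tested with limma's camera at a preset correlation of 0.01, which compares a list with other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were alternatives. P-values were adjusted over the 29 lists.

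Genes were named by a rule fixed before the data were examined. It took Bmal1, the clock genes past the threshold, up to 4 members of each other list with the smallest adjusted p, the 10 largest rises and 10 largest falls among genes with a mean of at least 100, no overlap between groups and a symbol that is not a predicted-gene name, and the 5 genes with the smallest adjusted p and the 5 with most reads. Some genes this rule takes are not reported here. Normalized counts stood in for the log CPM of that rule. Srf, Tpm1, Myocd, Runx2, Gapdh, Xist, Pabpc1, Lars2, Insc, Cyp2r1, Rras2, Pde3b, the genes of the Hox, Igf, prolactin, calcitonin and class II histocompatibility groups and the members of lists that did not pass were named after their values were seen. Myocd, Rras2 and Pde3b were not run under the alternatives described below. Of the 27179 Gene IDs, 25275 (93.0%) matched a RefSeq table of the same build, which gave coordinates and the symbols of 1933 of the 3829 genes listed without one. Coordinates are whole genes, counted from 1.

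Replicates of a group were checked for duplicates and differed by more than sampling noise in every pair. Alternatives fixed beforehand were other scalings, no filter and a stricter filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, DESeq2 and voom. The edgeR test with TMM, planned as the main one, became an alternative once the unit was known. Added after seeing the data were TMM scaling in limma, pseudocounts of 0.5 and 5, leaving out X- and Y-linked genes, and removing a loess trend of log2 fold change on transcript length and GC content (span 0.4) over the 14848 tested genes with a length. The trend was removed first as fitted, which moved the median log2 fold change of all genes from 0.011 to -0.24, and then with that median kept, because the shift is not part of the trend. Both are reported. The test was tried on simulated counts for 15865 genes with 200 changed. It recovered 34.3% of the 67 genes changed 1.5-fold, 77.6% of the 67 changed 2-fold and 95.5% of the 66 changed 4-fold, and called 7 unchanged genes.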

Results

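Messenger RNA was sequenced from primary mouse vascular smooth muscle cells, the contractile cells of the artery wall, taken from the aorta and grown in culture. There were 6 libraries, 3 labelled wild type (WT) and 3 labelled Bmal1 KO. Bmal1, which the gene table lists under its older symbol Arntl, encodes the transcription factor that pairs with CLOCK to drive the circadian clock. All cultures had been kept for 7 days in a medium that the labels call diabetic, with hydrogen peroxide at 0.3 mM and glucose at 4.5 g/L. The single comparison the design implies is between the genotypes in this medium. Libraries from other media or times were not analysed here. Reads assigned to genes came to 40850549, 44657471 and 39129037 in WT replicates 1, 2 and 3, and to 38074293, 32503525 and 33738702 in Bmal1 KO replicates 1, 2 and 3. Values are normalized read counts, and ± gives the SD over the 3 libraries of a group. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

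Bmal1 mRNA was not lower in the libraries labelled Bmal1 KO. The gene (chromosome 7, 113178471 to 113314126 in the mm10 build) rose from 579 ± 45.7 to 1005 ± 54.9 normalized counts (SD, n = 3), a 1.73-fold difference (log2 fold change 0.79, SE 0.091, limma with Benjamini-Hochberg adjusted p = 0.000135). All 3 libraries labelled Bmal1 KO, at 1036, 941 and 1036, lay above the WT libraries at 529, 619 and 590.4. Counts are summed over the whole gene, so they cannot show whether a deleted exon is missing from the transcript. Gene-level counts of Bmal1 therefore neither show nor exclude the knockout that the group label states. Every direction given here is between the libraries labelled Bmal1 KO and the WT libraries.

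Genes that CLOCK and BMAL1 transcribe moved both ways. The phase of the clock at harvest was not examined, so a difference in phase cannot be told apart from a difference in level. Of 15 such targets, 5 rose and 8 fell in the libraries labelled Bmal1 KO, and Dbp (511 ± 34.1 in WT and 443 ± 73.8 in Bmal1 KO) and Per3 (160.4 ± 19.3 and 208 ± 59.7) did not pass the test. Nr1d2, which encodes the repressor REV-ERB beta, rose 4.89-fold, from 285 ± 34.4 to 1391 ± 97.4 (SD, n = 3, adjusted p = 1.59e-06). The period gene Per1 rose 2.07-fold, the deubiquitinase gene Usp2 1.82-fold, Nr1d1 1.60-fold and the cryptochrome gene Cry2 1.39-fold. The Cry2 call was lost when a trend on transcript length and GC content was removed without keeping the median of all genes (adjusted p = 0.242). The other cryptochrome gene, Cry1, fell most by fold, 6.30-fold, from 3952 ± 50.1 to 627 ± 59.3 (adjusted p = 1.44e-07). Hlf was 4.43-fold lower, Bhlhe40 2.61-fold, Bhlhe41 2.04-fold, Ciart 1.74-fold, Per2 1.69-fold and Tef 1.55-fold. The list as a whole, with a median log2 fold change of -0.63, did not stand apart from other genes (camera adjusted p = 0.479). Among 10 other clock genes, Clock itself rose 2.33-fold, from 1057 ± 94.0 to 2465 ± 109.9, and 4 fell. Those were Npas2, a paralog of Clock, by 5.43-fold, Csnk1e by 2.17-fold, Arntl2 by 2.17-fold and Nfil3 by 1.99-fold, while 5 did not pass (list camera adjusted p = 0.265).

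**Figure D1:**
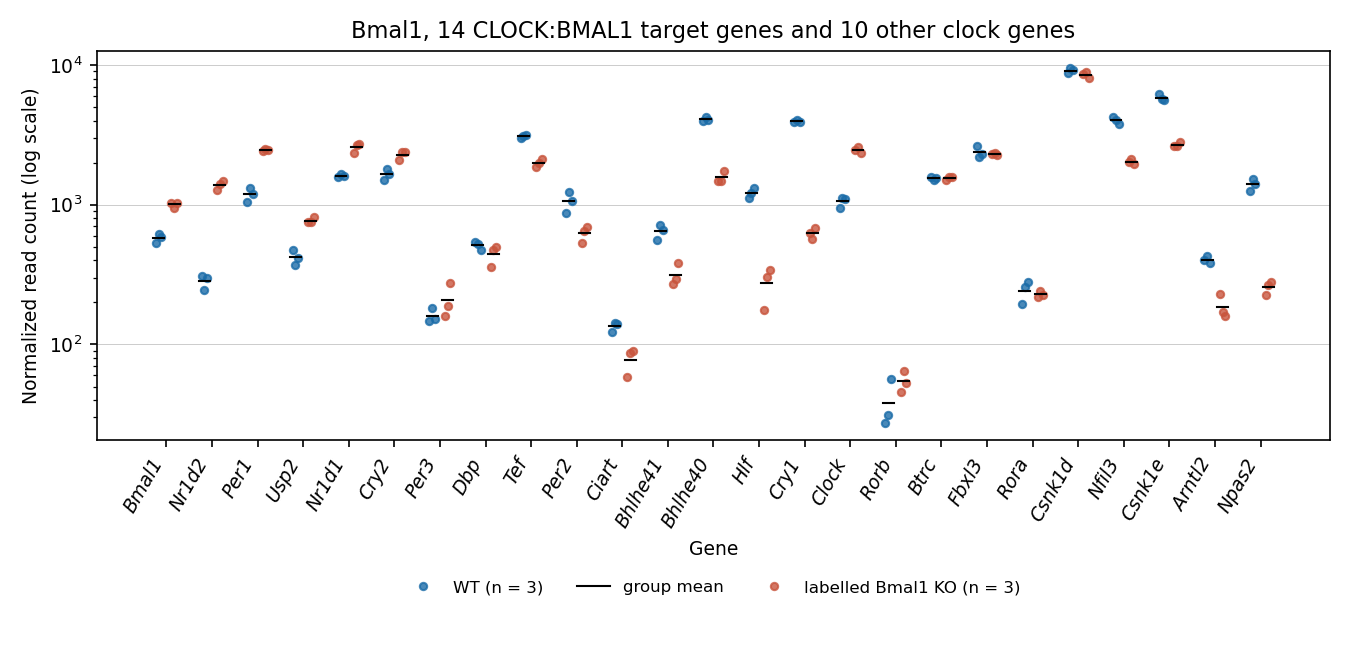
Normalized read counts (log axis) of Bmal1, 14 of the 15 CLOCK:BMAL1 target genes and 10 other clock genes in each of the 3 WT and 3 Bmal1 KO libraries, with a line at each group mean. Bmal1 lies at a mean of 1005 in the libraries labelled Bmal1 KO and 579 in WT, and the targets lie on both sides of their WT levels.

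The libraries of the 2 labels also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome in female cells (chromosome X, 103460373 to 103483233), rose from 58.7 ± 40.8 to 3867 ± 23.1 (log2 fold change 6.43, SE 0.64, adjusted p = 6.09e-05). Without WT replicate 2 its log2 fold change was 5.55. The Y-linked genes fell in the libraries labelled Bmal1 KO, Ddx3y from 3109 ± 285 to 77.1 ± 7.53, Eif2s3y from 2178 ± 389 to 101 ± 22.8, Kdm5d from 1286 ± 156 to 49.96 ± 23.6 and Uty from 648 ± 79.1 to 26.1 ± 11.3. Genotype label and sex-linked expression separate the same 3 libraries from the same 3, so each gene group in the following paragraphs moved together with Xist and the Y-linked genes. The Y-linked genes have X-linked relatives of similar sequence, so a few of their reads are uncertain. The labels give no sex for the mice.

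**Figure D2:**
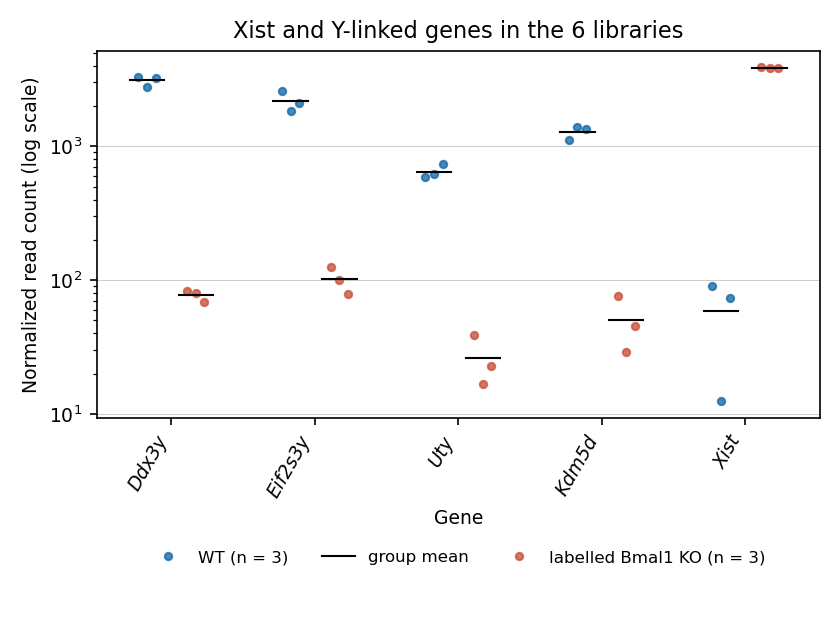
Normalized read counts (log axis) of 4 Y-linked genes and Xist in each of the 3 WT and 3 Bmal1 KO libraries, with a line at each group mean. Xist has a mean of 58.7 in WT and 3867 in the libraries labelled Bmal1 KO, and the Y-linked genes lie the other way round.

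Differences reached most expressed genes. Of 16086 genes tested, 11435 passed the threshold (71.1%), 5816 higher and 5619 lower in the libraries labelled Bmal1 KO, and 5371 of them differed at least 2-fold (3306 higher and 2065 lower). Removing a trend on transcript length and GC content without keeping the median of all genes, which moved that median from 0.011 to -0.24, gave 4260 higher and 7090 lower. With the median kept, 5557 were higher and 5181 lower. The median-ratio scaling assumes that most genes do not differ, or differ evenly, so it partly sets the near-even split. TMM scaling gave 5438 higher and 6146 lower, and upper-quartile scaling 6142 higher and 5219 lower. The first principal component held 88.7% of the variance and separated the groups. Counts of the 3 WT libraries did not overlap those of the 3 others in 76.7% of tested genes, where chance gives 10%.

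The largest rises were in genes at or near 0 in WT. Calcb, which encodes a calcitonin gene-related peptide (chromosome 7, 114716555 to 114723368), had no reads in any WT library and 11469 ± 208 normalized counts in the libraries labelled Bmal1 KO (SD, n = 3), at least 12929.6-fold higher against a floor of 3 reads over the WT group. The flavin monooxygenase gene Fmo2 (chromosome 1, 162874317 to 162898758) rose from 7.08 ± 0.554 to 32815 ± 2281, or 4633-fold. The carboxypeptidase gene Folh1 rose from 16.0 ± 2.88 to 24595 ± 1288, and Psca from 10.98 ± 6.35 to 5175 ± 302. Members of the prolactin family rose as well, Prl2c3 from 10.7 ± 2.78 to 35525 ± 769.6 and Prl8a2 from no reads to 1301 ± 204, at least 1466-fold higher. Prl2c3 has near-identical copies, so its level is uncertain. The mast cell tryptase gene Tpsab1 and H2-M1, a nonclassical histocompatibility gene, also had no WT reads and were at least 769-fold and at least 717-fold higher. The homeobox gene Lhx8 had 2 reads in WT against 2437, a ratio of 1487 with a 95% counting interval of 424 to 12654, and both WT reads were in replicate 1. The smallest adjusted p-values included those of Fmo2 (adjusted p = 9.78e-10) and of the neuropeptide receptor gene Adcyap1r1, 44.2-fold higher (adjusted p = 3.20e-09).

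The largest falls included genes of inflammation and 2 hormone genes. The neutrophil chemokine gene Cxcl5 (chromosome 5, 90759298 to 90761625) fell from 26086 ± 5129 to 9.76 ± 4.89 (SD, n = 3), 2673-fold lower (adjusted p = 6.66e-08). Nos2, the inducible nitric oxide synthase gene, fell from 2795 ± 372 to 4.16 ± 1.60, a 672-fold difference. Cxcl1 and the acute-phase gene Saa3 fell 419-fold and 305-fold. Fgf23, which encodes a hormone of phosphate balance, fell from 1692 ± 242 to 6.06 ± 3.04 and Fgf21, a metabolic hormone gene, from 578 ± 94.9 to 5.13 ± 5.14, or 113-fold (75.2-fold without Bmal1 KO replicate 2 and 227-fold without 3). The ATP-gated channel gene P2rx3 fell 126-fold, the transcription factor gene Trp63 130.2-fold, Nlrp2 187-fold and X-linked Xlr3b 247-fold, which has close copies that make its level uncertain. Nlrp2 had 5 reads and Xlr3b 8 in the libraries labelled Bmal1 KO, so these folds have 95% counting intervals of 80.8 to 583 and 118 to 542. Without Bmal1 KO replicate 2 or 3 the Nlrp2 fold was 344 or 124, and without Bmal1 KO replicate 1 the Xlr3b fold was 594. Among the genes with most reads, the elongation factor genes Eef1a1 and Eef2 fell 2.29-fold and 3.06-fold, Fn1 2.02-fold and mt-Co1 1.46-fold. A gene listed only under NCBI Gene ID 100861531 rose 1.77-fold (adjusted p = 0.0226), and this call was lost without Bmal1 KO replicate 1 (adjusted p = 0.0598), 2 (adjusted p = 0.0822) or 3 (adjusted p = 0.0517).

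Contractile genes of smooth muscle were higher in the libraries labelled Bmal1 KO. Of 22 genes in this list, 19 rose, Srf and Tpm1 fell and 1 did not pass, with the same counts when adjusted over the list alone. Tagln, which encodes the actin-binding protein SM22, rose from 5410.0 ± 909 to 32334 ± 2432 (SD, n = 3, 5.98-fold, adjusted p = 1.12e-06). Cnn1 (calponin) rose 4.47-fold and Acta2 (smooth muscle alpha-actin) from 20688 ± 1364 to 62931 ± 1900.4, or 3.04-fold. Srf, the transcription factor that drives many of these genes, fell 1.39-fold and Tpm1 1.27-fold. Myocd (myocardin), also in the list, had a log2 fold change of 4.81 (adjusted p = 0.000157). It had only 9 reads in WT, with normalized counts of 6.42, 0.829 and 0.921, against 223 reads in Bmal1 KO. The list's median log2 fold change was 1.43 (camera adjusted p = 3.34e-05). The call was lost with the correlation taken from the data (adjusted p = 0.214 with an estimated correlation).

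Bone and cartilage genes moved both ways. Of 18 tested, 7 rose, 8 fell and 3 did not pass, also when adjusted over the list alone. Spp1, which encodes osteopontin, rose from 25551 ± 2585 to 130165 ± 3738 (SD, n = 3, 5.09-fold), and the cartilage matrix gene Comp rose 10.9-fold. Bmp4 fell from 1765 ± 24.9 to 212 ± 42.8 (8.32-fold), Col11a1 moved by a log2 fold change of 1.63 (adjusted p = 1.44e-06), and Runx2, the main bone transcription factor, fell 1.19-fold (adjusted p = 0.0138). The Runx2 call was lost without Bmal1 KO replicate 1 (adjusted p = 0.0535) or 2 (adjusted p = 0.0538), and with the length and GC trend removed and the median kept (adjusted p = 0.113). The median was -0.19 and the mean 0.18 on the log2 scale, with opposite signs, and camera gave an adjusted p of 0.961. The direction of that test turned without WT replicate 1 (list median -0.013) or WT replicate 3 (-0.15). Bglap, Ibsp, Acan, Dmp1 and Sost had too few reads to be tested. Of 12 genes that restrain calcification or carry phosphate, 7 rose, 3 fell and 2 did not pass (camera adjusted p = 0.372). Mgp, which encodes the calcification inhibitor matrix Gla protein, rose from 11762 ± 3292 to 146584 ± 18518 (12.5-fold), Gas6 rose 2.01-fold, Fbln5 had a log2 fold change of -1.11, and Nt5e fell 2.84-fold.

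Collagen and elastic fibre genes were mostly higher. Of 33, 25 rose, 6 fell and 2 did not pass, and the median log2 fold change was 1.05 (camera adjusted p = 0.000199, and adjusted p = 0.621 with an estimated correlation). Postn (periostin) had a log2 fold change of 4.39, Ccn2 of 3.99, the microfibril gene Mfap5 of 3.04 and the collagen VI gene Col6a3 of 5.74, from 949.9 ± 189 to 50186 ± 4262 (SD, n = 3). Fibronectin, Fn1, fell 2.02-fold. Matrix proteases and their inhibitors split, with 12 of 25 higher, 11 lower and 2 not passing (camera adjusted p = 0.709). The gelatinase gene Mmp2 fell from 46936 ± 4332 to 2195 ± 73.7, or 21.4-fold, and the urokinase gene Plau fell 5.42-fold. Adamts1 rose from 2252 ± 215 to 45485 ± 3153, or 20.2-fold.

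Inflammatory cytokine and adhesion genes were lower in the libraries labelled Bmal1 KO. Of 23 tested, 3 rose, 19 fell and 1 did not pass, with a median log2 fold change of -2.74 (camera adjusted p = 1.64e-06, and adjusted p = 0.214 with an estimated correlation). Saa3 fell from 65679 ± 14949.9 to 215 ± 41.8 (SD, n = 3), Cxcl1 from 27166 ± 1436 to 64.8 ± 14.6, and Ccl2, which draws monocytes, from 27582 ± 4738 to 967 ± 81.3, or 28.5-fold. Lcn2, a siderophore-binding protein gene, fell 16.0-fold. Interferon-response genes did not stand apart as a list (16 of 30 higher, 5 lower, 9 not passing, camera adjusted p = 0.114). Gbp2 had a log2 fold change of 1.38, Irgm1 of 1.204 and Parp14 of 1.36.

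Genes of glycolysis and the response to low oxygen were lower. Of 26, 2 rose, 22 fell and 2 did not pass, with a median log2 fold change of -1.40 (camera adjusted p = 3.35e-07, and adjusted p = 0.384 with an estimated correlation). Vegfa, the endothelial growth factor gene, fell from 22934 ± 1119 to 1803 ± 183 (SD, n = 3), or 12.7-fold. Pdk1, whose product inhibits pyruvate dehydrogenase, fell 10.4-fold, the lactate transporter gene Slc16a3 6.30-fold and the phosphofructokinase gene Pfkl 5.36-fold. Gapdh also fell, but its many pseudogenes make its counts uncertain. Oxidative phosphorylation genes were mostly lower too. In that list 1 of 33 rose, 23 fell and 9 did not pass, with a median of -0.50 (camera adjusted p = 0.000947, and adjusted p = 0.711 with an estimated correlation). With the length and GC trend removed and the median of all genes kept, the median was -0.30 and the call was lost (adjusted p = 0.0504). Its members Cyc1, Uqcrc2, Atp5a1 and Cox4i1 had log2 fold changes of -0.84, -0.56, -0.62 and -1.35.

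Cholesterol and fatty acid synthesis genes were higher on balance, with 13 of 25 up, 2 down and 10 not passing (median log2 fold change 0.58, camera adjusted p = 0.0193, and adjusted p = 0.488 with an estimated correlation). With the length and GC trend removed, this median was 0.23 with the median of all genes kept (adjusted p = 0.0406) and -0.019 without, where the call was lost (adjusted p = 0.0825). Hmgcs1 had a log2 fold change of 1.12, Stard4 of 2.15 and Nsdhl of 1.84. The medium contained hydrogen peroxide. The antioxidant list, which joins targets of the regulator NRF2 with other antioxidant genes, moved both ways, 7 of 27 higher, 10 lower and 10 not passing (camera adjusted p = 0.657). Gclc, which encodes a subunit of the enzyme that starts glutathione synthesis, had a log2 fold change of 2.09, Nqo1 of 2.24, Sod2 of -2.06 and Gpx3 of 4.82. Of 9 NADPH oxidase genes, whose products make superoxide or hydrogen peroxide, 7 rose and 2 fell (camera adjusted p = 0.150). Nox4 went from 420.4 ± 16.97 to 1781 ± 82.9 (SD, n = 3, log2 fold change 2.08), and Duox1 and Cybb had log2 fold changes of -3.08 (-3.59 without Bmal1 KO replicate 2) and 2.12.

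Cell cycle genes were higher and p53 and senescence genes lower. In the proliferation list 20 of 30 rose, 4 fell and 6 did not pass (median log2 fold change 0.56, camera adjusted p = 0.00303, and adjusted p = 0.384 with an estimated correlation). Removing the length and GC trend lowered this median to 0.43 with the median of all genes kept and to 0.18 without (adjusted p = 0.00479 and adjusted p = 0.00800). Rrm2, Plk1, Ccna2 and Cenpf had log2 fold changes of 2.96, 1.45, 1.15 and 1.73. Of 20 p53 and senescence genes, 4 rose, 13 fell and 3 did not pass (median -0.72, camera adjusted p = 0.00634, and adjusted p = 0.564 with an estimated correlation). Gdf15, a stress-induced cytokine gene, went from 3316 ± 459 to 275 ± 10.4 (SD, n = 3), and Sesn2, Bbc3 and Mdm2 had log2 fold changes of -1.41, -2.19 and -1.34. Endoplasmic reticulum stress genes split, 9 of 20 up and 8 down (10 and 8 adjusted over the list alone), with a positive median (0.18), a negative mean (-0.50) and a downward test (camera adjusted p = 0.673). Those of the ATF4 branch that carried the smallest p-values, Trib3, Chac1, Asns and Atf4, had log2 fold changes of -3.37, -3.36, -1.43 and -1.81.

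Camera called none of 3 further stress and turnover lists, while fry, which does not compare a list with other genes, called the autophagy list (adjusted p = 0.00145) and the immediate early list (adjusted p = 0.00462). In the autophagy and lysosome list 4 of 22 rose, 9 fell and 9 did not pass (camera adjusted p = 0.130), and Neu1, Tfeb and Sqstm1 had log2 fold changes of -1.35, -1.12 and -0.73. Immediate early genes gave 6 of 17 higher, 8 lower and 3 not passing (adjusted p = 0.451), with Egr1 at -2.23, Fos at 1.49, Dusp1 at 1.64 and Ier3 at -1.77. Heat shock genes gave 3 of 12 higher, 7 lower and 2 not passing (adjusted p = 0.479), with Hspb1 at 3.05 and Hspa1b, which has a near-identical copy, at -0.59. Hspd1 (-0.79) and Hspe1 (-1.33) overlap at their starts, so reads there are uncertain.

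In the list of TGF-beta and BMP signalling, 13 of 24 genes rose and 7 fell (13 and 8 adjusted over the list alone), and camera gave an adjusted p of 0.215. The coreceptor gene Tgfbr3 had a log2 fold change of -1.91, the inhibitory Smad gene Smad6 of 2.50 and Id4 of 5.09. Of 24 Wnt signalling genes, 16 rose and 6 fell (16 and 7 adjusted over the list alone), with a camera adjusted p of 0.0563. That list gained a call in 6 other camera settings (adjusted p from 0.0207 to 0.0495). Sfrp2, which encodes a secreted Wnt binder, went from 88.1 ± 7.73 to 592 ± 24.1 (SD, n = 3), and Wnt5a, Nkd1 and Nkd2 had log2 fold changes of -2.05, 2.85 and 2.15. The remaining 27 of 30 lists had the same counts adjusted over the list alone as over all genes tested.

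Markers of other cell types also differed between the labels. Of 12 endothelial markers 9 rose, 1 fell and 2 did not pass (median log2 fold change 1.92, camera adjusted p = 0.0478, and adjusted p = 0.564 with an estimated correlation). Eng went from 6019.5 ± 598 to 11465 ± 567 (SD, n = 3) and Pecam1 from 34.7 ± 22.1 to 264 ± 56.3, or 7.59-fold (11.4-fold without WT replicate 3), and Emcn and Egfl7 had log2 fold changes of 2.33 and -1.34. Of 16 macrophage and leukocyte markers, 13 rose, 2 fell and 1 did not pass (median 2.30, camera adjusted p = 0.0265, and adjusted p = 0.711 with an estimated correlation). Csf1r went from 216 ± 32.8 to 893 ± 14.6, Mrc1 from 5.42 ± 2.58 to 57.7 ± 7.37, Cd68 from 348 ± 54.3 to 74.0 ± 13.4 and Cd14 from 2886 ± 307 to 404 ± 24.1. All 7 tested Schwann cell and neural markers rose (median 2.32, camera adjusted p = 0.0113, and adjusted p = 0.564 with an estimated correlation), among them Tubb3 from 1148 ± 202 to 3126 ± 229, Ncam1 from 2518 ± 219.8 to 4329 ± 68.5, S100b from 48.8 ± 17.7 to 262 ± 27.7 and Gfap from 44.0 ± 6.18 to 138 ± 29.9. The endothelial call was lost without WT replicate 1 (adjusted p = 0.0645), WT replicate 2 (0.0502), Bmal1 KO replicate 1 (0.0547) or 3 (0.0590), where the list median was 2.03, 1.52, 2.18 and 1.70. It was also lost with the length and GC trend removed and the median of all genes kept (adjusted p = 0.0682), although the list median did not shrink (1.96). The macrophage call was lost without WT replicate 1 (adjusted p = 0.0521, list median 2.42).

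The other marker lists split. Fibroblast markers gave 10 of 16 higher and 6 lower (camera adjusted p = 0.351), with Dcn from 26319.5 ± 1947 to 2403 ± 77.2 (SD, n = 3), Dpep1 from 67.3 ± 13.3 to 7794 ± 375 and Fbln1 from 6103 ± 506 to 706 ± 19.9. Mesothelial and epithelial markers gave 6 of 11 higher, 4 lower and 1 not passing (adjusted p = 0.479), with Msln from 356 ± 26.3 to 4525 ± 132, and with Upk1b, Upk3b and Krt7 at log2 fold changes of 2.50, -2.49 and 1.65. Adipocyte markers gave 4 of 6 higher and 2 lower (adjusted p = 0.551), with Fabp4, Lipe, Pnpla2 and Pparg at 1.74, -1.09, -0.49 and 0.72. Striated muscle markers gave the same counts, 4 of 6 higher and 2 lower (adjusted p = 0.551), with Tnnt2, Tnni3, Ryr2 and Myh7 at 4.002, -2.55, 2.62 and 2.21. Across the 29 lists tested, 11 passed camera with its preset correlation, 7 upward and 4 downward. With an estimated correlation 0 passed, and the smallest adjusted p was 0.214. With fry 25 passed. Of these, 12 gained a call in camera's direction, and the bone and cartilage and protease lists passed in the other direction.

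**Figure D3:**
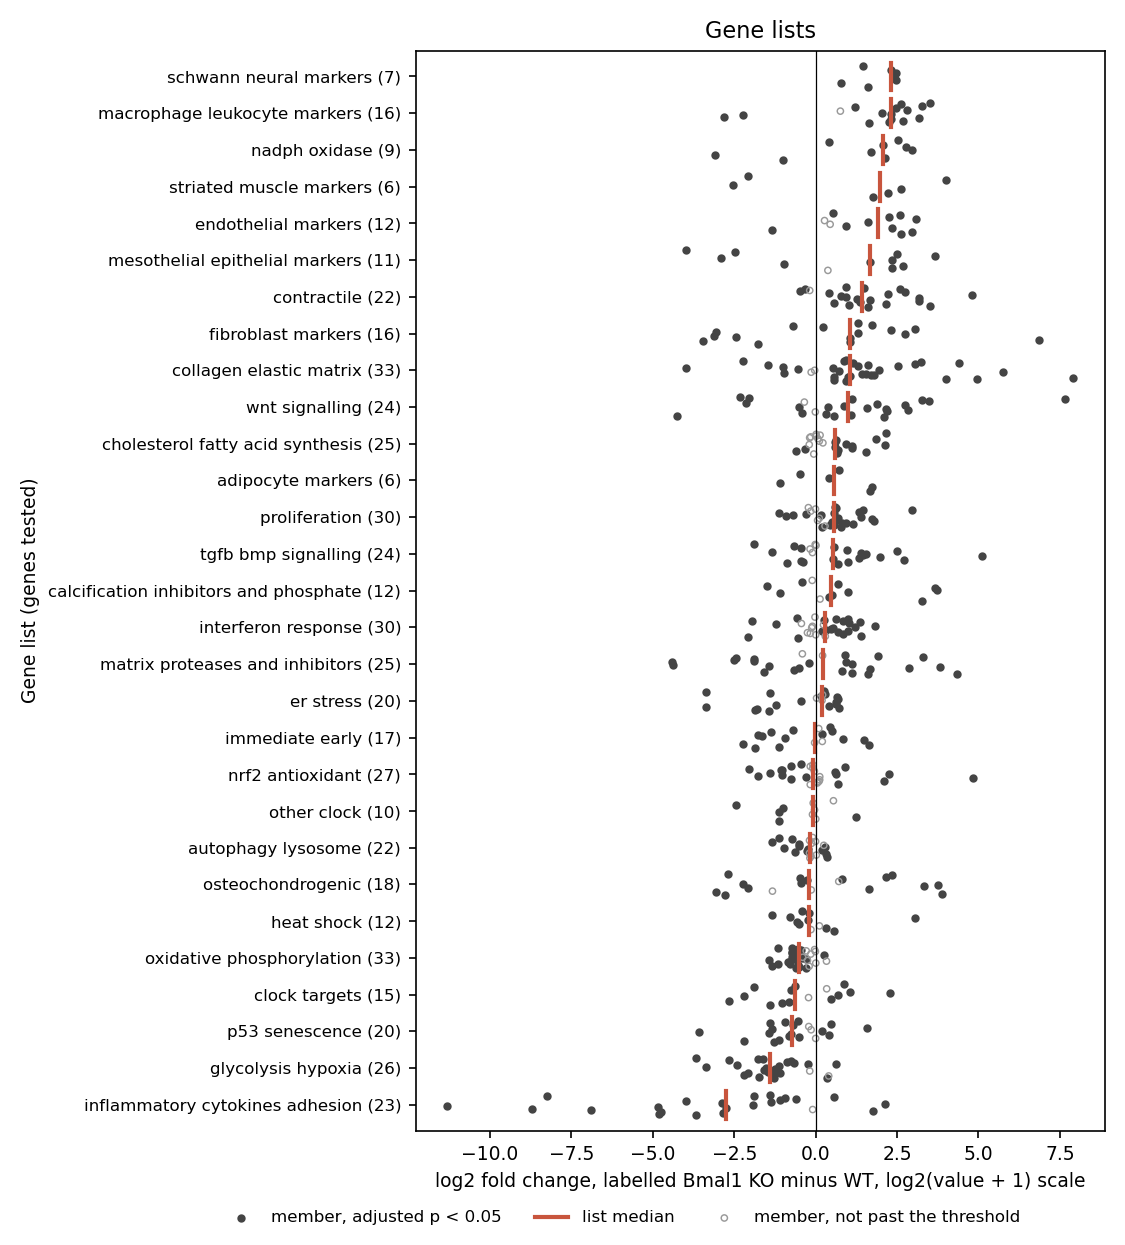
Log2 fold changes (Bmal1 KO minus WT, on the log2(value + 1) scale) of each tested member of 29 gene lists, with the number tested in brackets, filled where the adjusted p passed the threshold, and a red line at the list median. Inflammatory genes have a median of -2.74, glycolysis and hypoxia genes of -1.40 and contractile genes of 1.43.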

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

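TMM scaling, other pseudocounts, leaving out X- and Y-linked genes and removing the length and GC trend were chosen after seeing the data, and edgeR, the planned main test, became an alternative once the unit was known. The count of genes past the threshold, 11435, ranged from 10353 to 12215 over the 14 alternatives that used all libraries (11485 with edgeR, 11267 with DESeq2, 11501 with voom, 11075 without X- and Y-linked genes) and from 10283 to 11692 with 1 library left out. The share of calls that were higher ran from 46.9% with TMM scaling to 54.1% with upper-quartile scaling, apart from 37.5% with the length and GC trend removed and the median of all genes not kept (50.9% as reported, 51.8% with the median kept). Bmal1 kept its direction and its call in 20 of 20 alternatives (log2 fold change 0.50 to 0.85). Of 194 genes run, 155 by the rule and 39 named after their values were seen, 3 lost a call. These were the gene listed under ID 100861531 in 3 settings that each left out 1 Bmal1 KO library, Runx2 without Bmal1 KO replicate 1 or 2 (adjusted p = 0.0535 and 0.0538) and with the trend removed and the median kept (log2 fold change -0.14, adjusted p = 0.113), and Cry2 with the median not kept (0.12, adjusted p = 0.242). Among those that did not pass, Per3 turned to -0.25 with the median not kept, and Igfbp7 to -0.023 with voom, -0.029 with edgeR, -0.053 with TMM scaling and -0.058 with the median not kept, and ran from -0.060 to 0.11 with 1 library left out. Emcn, Myh7, Prl and Hoxa9 had no value under the stricter filter, the named X- and Y-linked genes none where those were left out, and the gene under ID 100861531, which lacks a length, none with the trend removed.

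The labels do not say that repeat numbers pair the libraries. Deviations of same-numbered libraries correlated at -0.0045, 0.026 and 0.084, and not every library correlated best with its own number. Such values show no pairing but cannot exclude one. With the number as a replicate block 11556 genes passed, and the bone and cartilage list, at a median of -0.19, had its test turn upward (adjusted p = 1.00).

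The bone and cartilage test also turned upward under the stricter filter (median 0.28), edgeR (-0.21), TMM scaling (-0.25), the trend removed with the median not kept (-0.43) and fry (-0.19), where only fry passed the threshold (adjusted p = 0.0207, with all other alternatives between 0.654 and 1.00). Its median ran from -0.35 to 0.028 with 1 library left out. The contractile list, at 1.43, lost its call with an estimated correlation (adjusted p = 0.214), and CLOCK:BMAL1 targets, at -0.63, gained one with fry (0.0325), which does not compare a list with other genes. With fry the directions of the protease (median 0.21, adjusted p = 0.0212) and antioxidant (-0.083, 0.811) lists turned, and the antioxidant test also turned with the trend removed and the median kept (0.14, adjusted p = 0.948). In all, fry passed 25 of 29 lists, 12 of them calls gained in camera's direction. Endothelial and macrophage marker calls were lost with the stricter filter (0.119 for both) and edgeR (0.167 for both), and the endothelial call with upper-quartile scaling (0.0640) and with the trend removed and the median kept (0.0682). The endothelial median, 1.92, was 1.60 with the stricter filter, 1.93 with edgeR, 1.97 with upper-quartile scaling and 1.96 with the trend removed, and the macrophage median, 2.30, was 2.30 with the stricter filter and 2.27 with edgeR. The oxidative phosphorylation call was lost with the trend removed and the median kept (median -0.30, adjusted p = 0.0504) and the cholesterol and fatty acid call with the median not kept (-0.019, 0.0825). The Wnt list gained a call under 6 camera settings (0.0207 to 0.0495) and the endoplasmic reticulum stress list under edgeR (0.0444). The causes were not tested.

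The simulation, at this depth with 3 libraries per group and 200 genes changed, recovered 34.3% of genes changed 1.5-fold. In the data 71.1% of tested genes passed, which makes the Benjamini-Hochberg threshold less strict than in the simulation. The simulated share therefore does not give the recovery in this comparison. A change of that size can still be missed, but how often is not known.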

Other observations

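Genes of the translation machinery were lower in the libraries labelled Bmal1 KO, in a group chosen after its values were seen. Of 77 ribosomal protein genes tested, 0 rose and 73 fell, with a median log2 fold change of -1.73 (unadjusted camera p = 1.05e-17 with the preset correlation, and unadjusted p = 0.210 with an estimated correlation). Because of that choice, these p-values are no independent test of a fall. WT replicate 1 was the highest WT library for 74 of the 77, at a median of 1.24 times the group mean, and Bmal1 KO replicate 1 the highest of its group for 61, at 1.12 times. Without WT replicate 1, 73 fell and the median was -1.56, and without Bmal1 KO replicate 1, 74 fell and it was -1.82. Pabpc1, the main poly(A)-binding protein gene, fell 2.82-fold. Many ribosomal protein genes have processed pseudogenes, so single members are uncertain. Lars2, a gene whose mouse annotation is known to hold sequence similar to ribosomal RNA, so that its reads are uncertain, rose from 62954 ± 20762 to 157654 ± 17104 (SD, n = 3, 2.50-fold, adjusted p = 0.00124). Homeobox genes of the Hox clusters, which mark position along the body, moved both ways, with 9 of 25 higher and 7 lower (median log2 fold change 0.17). Of all genes tested 71.1% passed, so this count does not set the Hox genes apart. The members given here were picked after their values were seen. Hoxc5 rose 31.7-fold, Hoxc8 6.98-fold and Hoxc6 5.46-fold, while Hoxa10 had a log2 fold change of -3.92 (-4.67 without Bmal1 KO replicate 1 and -2.93 without 2) and Hoxa9 of -1.56. Hoxb13 had 224 reads in WT and 1, in replicate 1, in the libraries labelled Bmal1 KO, a ratio of 195 with a 95% counting interval of 31.7 to 7070.1.

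The growth factor gene Igf2 fell from 22167 ± 2519.9 to 1195 ± 51.7 (SD, n = 3), and Igf2bp1 and Igf2bp3, whose products bind its RNA, fell 7.95-fold and 9.42-fold. Of 6 binding protein genes, Igfbp2, Igfbp3, Igfbp5 and Igfbp6 rose 6.35-fold, 3.77-fold, 343-fold and 49.1-fold, Igfbp4 fell 1.89-fold, and Igfbp7, at 41163 ± 5349.8 in WT and 41168 ± 1131 in Bmal1 KO, did not pass (adjusted p = 0.950) and had no stable sign over the scalings. Igfbp5 had WT values of 82.5, 20.7 and 146, and its rise was 551-fold without WT replicate 3 and 8.01 on the log2 scale, against 8.79, without WT replicate 2. Imprinted Grb10 rose 13.7-fold while imprinted Dlk1 fell 8.70-fold. All 6 prolactin family and prolactin receptor genes examined rose, Prl from no reads to 36.4 ± 6.41 and Prlr from 30.0 ± 19.5 to 247 ± 59.1. They were picked after their values were seen and include the close copies Prl2c2, Prl2c3 and Prl2c5, so this count is not a test. Beside Calcb, the related Calca rose from 1.44 ± 0.906 to 1049 ± 42.6 from 5 WT reads, 727-fold with a 95% counting interval of 304 to 2192 (1141-fold without WT replicate 2), and the receptor genes Calcrl, Ramp1 and Ramp2 rose 7.79-fold, 6.62-fold and 6.39-fold (Ramp2 10.2-fold without WT replicate 3), while Ramp3, at 158 ± 30.5 in WT and 124 ± 3.55 in Bmal1 KO, did not pass (adjusted p = 0.121). Calca and Calcb both lie within 2 Mb of Bmal1 on chromosome 7. The class II histocompatibility genes H2-Aa, H2-Ab1 and H2-Eb1 rose together with Cd74, by 3.00, 2.98, 2.07 and 2.30 on the log2 scale. H2-Aa was at 2.28 without WT replicate 2 and 3.60 without WT replicate 3, and H2-Ab1 at 2.39 without WT replicate 2. Markers of macrophages and leukocytes, of which Cd74 is one, rose alongside in 13 of 16 cases while Cd14 and Cd68 fell, and WT replicate 2 was the lowest library for H2-Aa (42.3 against 139 and 269) as for Csf1r (184 against 216 and 249.6). Xist was lowest in that WT library too, and its rise went from 65.9-fold to 47.3-fold without it. Whether these differences among WT libraries share a cause was not tested. These genes, too, were chosen after their values were seen.

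In the tests that follow, those of the labels, the partial transcript, the mixing of libraries, the neighbours of Bmal1 and the length and GC content of ribosomal protein genes were chosen after the result was seen, and those of length and GC content for the oxidative phosphorylation and collagen lists and of the splits before. Keeping the median of all genes in the length and GC tests was chosen after seeing the data.

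Bmal1 mRNA was 1.73-fold higher where a knockout label is given. If the labels of the groups had been exchanged, the CLOCK:BMAL1 targets may be expected to be mostly higher in the libraries labelled Bmal1 KO. Of the 15, 5 were higher and 8 lower, which leaves an exchange open. The phase of the clock at harvest was not examined, so this count cannot decide the question. A transcript that lacks only part of the gene could keep a gene-level fold of 1.73, and since counts per exon were not used here, this cannot be told apart from an intact gene. Genes within 2 Mb of Bmal1 on chromosome 7 had a median absolute log2 fold change of 0.90 over 19 genes, at percentile 88.2 of such windows. Among them Rras2, Pde3b, Cyp2r1, Calca, Calcb and Insc, in chromosome order, had log2 fold changes of 2.40, 1.45, 4.83, 8.81, 13.5 and 5.14. They were listed here after their values were seen, and directions of the other genes in the window are not given. The window leaves a local effect of the altered locus or of its flanking chromosome open.

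Most genes differed, together with Xist and the Y-linked genes, and 71.5% of autosomal genes passed the threshold. Reads of one group mixed into the other do not account for the low Y-linked signal of 2.48% to 4.65% of WT in the libraries labelled Bmal1 KO, because 7 abundant autosomal WT genes, Cxcl5 at 0.0374% among them, lay below the lowest Y-linked share by more than a factor of 2 in every such library. Nor do they account for Xist in WT at 1.52% of the level in the other group (0.322% to 2.32% over the WT libraries), since 9 abundant autosomal genes, Calcb at 0 among them, lay as far below it. Other sources of the Xist reads in WT were not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one with 11435 genes, gave as many and the highest other gave 0, too few splits for a share under 0.05. A difference between cell isolates or in the sex of the mice may account for the breadth, was not tested, and cannot be separated from the genotype label in this design.

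The oxidative phosphorylation and ribosomal protein genes, which have short transcripts, were lower and the long collagen and matrix transcripts higher, so a trend with transcript length or GC content may contribute. Across 14848 genes, log2 fold change had Spearman correlations of 0.17 with length and -0.041 with GC content, where genes are not independent replicates. After a loess trend on both was removed with the median of all genes kept, the medians were 1.08 for collagen and elastic matrix and -1.47 for ribosomal proteins. Before, they were 1.05 and -1.73. Medians of this size argue against the fitted trend as the whole cause of these 2. They leave a difference between the genotypes, the isolates or the sexes open. After removal, camera with the preset correlation gave an adjusted p of 0.00118 for the collagen list. For the ribosomal genes, chosen after their values were seen, it gave an unadjusted p of 2.07e-15. With an estimated correlation, before the trend was removed, neither passed in camera (adjusted p = 0.621 and unadjusted p = 0.210). The oxidative phosphorylation median went from -0.50 (SD 0.41 over its members) to -0.30 (SD 0.39), and its call ended (adjusted p = 0.0504), for a cause that was not tested, so the trend stays open for this list. Without keeping the median of all genes, which moved it to -0.24, the medians were 0.83, -1.72 and -0.56 in the same order, and the oxidative phosphorylation list passed (adjusted p = 0.0242).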
